A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

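Total RNA of log-phase budding yeast grown in rich glucose medium was extracted with hot phenol, depleted of ribosomal RNA and sequenced as paired ends on an Illumina instrument, per the labels' protocols. The authors deposited a table of raw counts per gene for the 12 libraries. Per the submitters' processing notes, STAR, featureCounts and deepTools were used with the build R64, and versions, settings and strandedness are not given in the sources used here.

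The table held 7150 genes, and 4 emptied lines were not used. Of the gene identifiers, 6441 matched a locus tag of the reference annotation of the same build and 709 did not, and 6429 of the matched genes lay within the interval of the table. The 12 ribosomal RNA genes, with 2 counts in all libraries together, were left out of library sizes and tests. The 115 gene models that lie wholly inside another on the same strand had 0 counts, as they would if reads shared by overlapping models were left out. The 136 named models that lie wholly inside another on the opposite strand alone had a median total of 717.5 counts, so by these values the counting used the strand. A further 298 such models without a symbol had a median total of only 17.5 counts. For each gene model the share of 50-base words found elsewhere in the genome was computed. Of 412 models with over 99% repeated words 278 had a count, with a median total of 11 against 6461.5 for models without repeated words, so members of near-identical families are uncertain. Library totals were 16378131 to 27230570 counts, and the limit that a count of 0 allows is 3 counts of the total, which covers counting error only.

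Groups were taken from the genotype in the labels. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM scaling and the filter filterByExpr, on the 12 libraries in 1 fit with 1 mean per group. It tested 6171 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. CPM values use library sizes scaled by TMM. Every pair of groups except snf2 and cyc8 was compared, and the interaction was the change from snf2 to the double mutant minus the change from wt to cyc8. Folds against a group without counts were computed against 3 counts per library, as CPM averaged over the libraries of the group.

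The 30 gene lists were fixed before the data were examined, as were the tests of genes and lists, the rule for named genes and the alternatives except that with protein-coding genes only. They are flocculins, DAN and TIR mannoproteins, PAU genes, Rox1-repressed hypoxic genes, hexose transporters, other sugars, gluconeogenesis and acetate use, peroxisomal fatty acid oxidation, trehalose and glycogen, general stress, osmotic stress, ribonucleotide reductase and Crt1 targets, the phosphate regulon, the iron regulon, a-specific genes, alpha-specific genes, meiosis, pheromone response, Swi-Snf subunits, repressors that recruit Tup1-Cyc8, glycolysis, tricarboxylic acid cycle and respiratory chain, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, histones, amino acid biosynthesis, sulfur and methionine, daughter cell separation and subtelomeric genes (within 20 kb of a chromosome end). The list of repressors that recruit Tup1-Cyc8 also holds TUP1 itself. Of the members sought, 1 was not found in the table. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 30 lists of a comparison, beside camera with an estimated correlation and fry. Where only 1 camera p is given for a list below 0.05, the call also held with an estimated correlation.

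A rule set which genes could be named in each comparison, and the text names only part of them. It listed CYC8, SNF2, TUP1, the marker genes and up to 4 members of each list with the largest changes. Also listed were the 10 highest and 10 lowest called genes with a mean of at least 10 CPM whose libraries do not overlap between groups (without this condition for the interaction). The last were FLO1, SUC2, HXT2, RNR3, ANB1, HEM13, INO1, SER3, HO, PHO84, PHO5, HSP12 and STE2. The rule also listed GAL1, which is not analysed here. Coordinates are 1-based and of build R64.

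The steps were tested on simulated counts with 200 changed genes. At an absolute log2 fold change of 1.5 the test recovered 89% in cyc8 against wt (6036 genes), 91% in snf2 against wt (6032), 95% in the double mutant against wt (6030), 92% against snf2 (6013) and 95% against cyc8 (6101). At 3 it recovered 100%, 97%, 100%, 99% and 99% in the same order, and false calls were 0, 1, 1, 2 and 0. Overlaps of comparisons with shared libraries were set beside 20 simulations of unchanged groups. The alternatives were RLE and upper-quartile scaling, other filters on low counts, a replicate block, fits of the compared libraries only, DESeq2 1.42.0, limma-voom, other thresholds, dispersions without the robust option, ribosomal RNA kept, protein-coding genes only and each library left out.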

Results

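RNA depleted of ribosomal RNA was sequenced from budding yeast in log phase, in rich glucose medium, in 12 libraries that the labels put in 4 groups. Cyc8 (also Ssn6) and Tup1 form a corepressor that DNA-binding proteins bring to promoters, and Snf2 is the ATPase of the Swi-Snf chromatin remodelling complex. The title of the series names the question, how the complexes act against each other in transcription. The groups are wild type (wt, n = 3), libraries labelled cyc8 (n = 3), libraries labelled snf2 (n = 2) and libraries labelled with both mutations (cyc8 snf2, n = 4). The wt and cyc8 libraries are labelled with the strain BY4741, of mating type a, and the snf2 and cyc8 snf2 libraries with the strain FY2083 or a derivative of it. The strain background therefore changed with the group whenever a library of the first pair was compared with one of the second. Each library held 16378131 to 27230570 counts, so that a gene without a count could have reached 0.11 to 0.183 CPM (counts scaled to the library size) before TMM scaling, by counting error only. With TMM scaling, which the levels below use, this limit averaged 0.129 CPM in wt, 0.146 in cyc8, 0.11 in snf2 and 0.165 in cyc8 snf2. Levels are mean CPM ± SD over the n libraries of a group, log2 fold changes are given ± SE, and p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the sources used here says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

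Principal component analysis separated the groups. PC1 held 60.2% of the variance and set the libraries labelled cyc8 (37.6 to 40.3) and cyc8 snf2 (23.8 to 26.2) apart from wt (-47.9 to -41.7) and snf2 (-41.9 and -41.8). PC2 (20.9%) set the libraries labelled snf2 (33.4 and 33.8) and cyc8 snf2 (12.4 to 15.5) apart from wt (-27.5 to -19.8) and cyc8 (-17.4 to -15.4). Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 6.73 to 81.69 over all pairs. The non-coding share of the counts was 16.9 and 17.5% in the libraries labelled snf2 and 10.8 to 15.6% in the others.

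**Figure D1:**
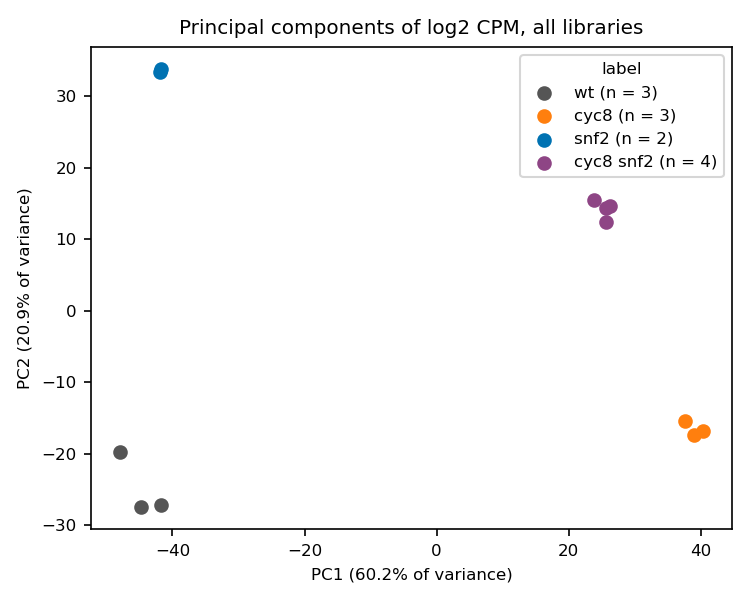
Scores of the 12 libraries on PC1 (60.2% of the variance) and PC2 (20.9%) of log2 CPM, 1 point per library and 1 colour per label. The libraries labelled cyc8 and cyc8 snf2 lie between 23.8 and 40.3 on PC1, and those labelled wt and snf2 between -47.9 and -41.7.

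The mutated genes were examined first, as a check of the labels. SNF2 (chromosome XV, 855147 to 860258) had 80.1 ± 8.21 CPM in wt, 79.6 ± 8.48 in cyc8, 66.0 ± 0.933 in snf2 and 109 ± 4.42 in cyc8 snf2. CYC8 (chromosome II, 462616 to 465972) had 77.1 ± 6.47, 59.3 ± 4.72, 61.5 ± 4.72 and 53.2 ± 2.58 CPM in the same order. Neither transcript was lost in the libraries labelled as its mutant: SNF2 differed from wt by a log2 fold change of -0.28 ± 0.10 in snf2 (edgeR adjusted p = 0.0485), and CYC8 by -0.38 ± 0.09 in cyc8 (edgeR adjusted p = 0.00304). A transcript from what the disruption left of a gene would be counted in the same way, and which part of each gene was replaced is not given in the sources used here. The groups are therefore called by their labels throughout. TUP1, which encodes the partner of Cyc8, stood at 244 ± 3.30, 226 ± 16.7, 173 ± 5.18 and 219 ± 7.96 CPM.

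The marker genes followed the genotypes in the labels, except that the transcripts of TRP1 and, in wt and cyc8, of HIS3 were not lost. LEU2, the marker of the snf2 mutation, had 483 ± 21.7 CPM in snf2 and 269 ± 69.7 CPM in cyc8 snf2, against at most 3 counts in any wt or cyc8 library. URA3, the marker of the cyc8 mutation in the double mutant, had 18.3 ± 1.24 CPM in cyc8 snf2 and no count in the cyc8 and snf2 libraries, which makes it at least 126-fold higher than in cyc8 and at least 167-fold higher than in snf2 (floor of 3 counts per library). HIS3 and LYS2, which the FY2083 label gives as deletions, had 44.2 ± 7.01 and 159 ± 5.65 CPM in wt and 0.0733 ± 0.00494 and 0.164 ± 0.0148 CPM in snf2. The BY4741 label also lists a his3 deletion allele, a different one, but HIS3 was not lost there, with 79.3 ± 13.6 CPM in cyc8. MET17, also called MET15 and a deletion in the labels of both backgrounds, had 0 to 18 counts per library. TRP1, of which the FY2083 label lists a mutant allele, was not lost (37.2 ± 2.03 CPM in wt, 47.5 ± 0.720 in snf2). An allele that removes only part of a gene would still be counted, so the HIS3 and TRP1 counts need not go against the labels. None of these genes is read as a response.

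The libraries labelled cyc8 were first compared with wt in the same strain, to ask which genes are held low when Cyc8 is present. The largest rises included cell wall, hypoxic and sugar uptake genes. FLO1, which encodes a lectin-like wall protein that makes cells clump, rose from 4.29 ± 0.821 to 722 ± 67.0 CPM, 169-fold. SUC2, which encodes the secreted invertase that splits sucrose, rose 48.3-fold, and RNR3, a subunit of ribonucleotide reductase induced by DNA damage, 55.7-fold. PHO84, the high-affinity phosphate transporter, fell from 1235 ± 169.6 to 67.9 ± 44.6 CPM. Of 6171 genes tested, 640 were higher and 215 lower in cyc8 than in wt at an adjusted p below 0.05 and a change of at least 2-fold. The CYC8 transcript itself was kept in these libraries, so each direction stands for the label. Upper-quartile scaling moved the median of all genes by -0.122 against the scaling used here, and the share of higher genes among those called from 74.9 to 68.3%.

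Flocculins and the wall proteins of cells without oxygen rose as groups. All 5 flocculin genes were higher (median log2 fold change 5.45, camera adjusted p = 2.4e-07). FLO1 (YAR050W, chromosome I, 203403 to 208016) (log2 fold change 7.40 ± 0.16, edgeR adjusted p = 3.27e-13) shares 53.8% of its 50-base words with other places in the genome, and FLO9 and FLO5 also have near copies, so their reads can be split. FLO11, which encodes the wall glycoprotein needed for pseudohyphal growth, went from 2.92 ± 0.627 to 127 ± 30.1 CPM (log2 fold change 5.45 ± 0.24, edgeR adjusted p = 1.8e-09). Of the PAU genes, a subtelomeric family of small wall proteins, 15 of 18 were higher (median log2 fold change 4.64, camera adjusted p = 2.2e-12). PAU24 reached 8338 ± 1698 CPM from 1.01 ± 0.208 and PAU13 3150.1 ± 405 CPM from 0.687 ± 0.241 (log2 fold change 12.15 ± 0.20, edgeR adjusted p = 3.34e-14), and members of this family can also exchange reads. PAU5, with 7.2% of its words repeated, rose 848-fold, to 1466 ± 116 CPM. PAU19 had no count in wt and was at least 206-fold higher in cyc8 (floor of 3 counts per library). All 6 DAN and TIR mannoprotein genes, expressed in anaerobic cells, were higher (median log2 fold change 6.69, camera adjusted p = 3.3e-08, adjusted p = 0.051 with an estimated correlation). DAN1 (chromosome X, 708704 to 709885), which has no repeated words, rose from 1.42 ± 1.10 to 1219.5 ± 165 CPM (log2 fold change 9.70 ± 0.40, edgeR adjusted p = 4.24e-09), and TIR1 from 65.2 ± 10.3 to 6006 ± 567 CPM. Of the hypoxic genes repressed by Rox1, 6 of 8 were higher (median log2 fold change 1.87, camera adjusted p = 0.00022, adjusted p = 0.062 with an estimated correlation). They included ANB1, the hypoxic form of translation factor eIF5A, at 17.4-fold, and HEM13, an enzyme of heme synthesis, at 10.1-fold.

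Sugar uptake and the use of other carbon sources rose as well. Of 16 hexose transporter genes tested, 13 were higher and 1 lower (median log2 fold change 3.11, camera adjusted p = 4.4e-08). HXT2 (chromosome XIII, 287567 to 289942), a high-affinity glucose transporter, rose from 359 ± 55.0 to 6907 ± 133 CPM (log2 fold change 4.27 ± 0.12, edgeR adjusted p = 2.28e-12). HXT17 and HXT13, near 0 in wt at 0.291 ± 0.170 and 0.256 ± 0.235 CPM, reached 610.3 ± 52.6 and 361 ± 29.9 CPM. Of the genes for other sugars, 13 of 16 were higher (median log2 fold change 2.41, camera adjusted p = 1.8e-09, adjusted p = 0.059 with an estimated correlation), among them SUC2 (chromosome IX, 37316 to 39203) (log2 fold change 5.59 ± 0.12, edgeR adjusted p = 2.09e-13) and IMA1, an isomaltase, at 80.1-fold. In the list of gluconeogenesis and acetate use, 9 of 16 were higher (median log2 fold change 1.25, camera adjusted p = 1.6e-06). JEN1, the lactate permease, rose 11.1-fold and PCK1, which opens gluconeogenesis, 7.60-fold. In the tricarboxylic acid cycle and respiratory chain 16 of 32 were higher (median log2 fold change 0.99, camera adjusted p = 8.4e-10, adjusted p = 0.12 with an estimated correlation), by smaller amounts, such as COR1 at 2.40-fold. In the glycolysis list 3 were higher and 1 lower of 17 (median log2 fold change 0.15, camera adjusted p = 0.55), and in the peroxisomal list 2 of 13 were higher (median log2 fold change -0.01, camera adjusted p = 0.52), where the mean was 0.38, on the other side of 0.

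Genes of the DNA damage and salt responses were also higher. In the list of ribonucleotide reductase and Crt1 targets 4 of 6 were higher (median log2 fold change 3.45, camera adjusted p = 2.4e-06). RNR3 (chromosome IX, 237955 to 241732) went from 10.3 ± 1.83 to 574 ± 61.1 CPM (log2 fold change 5.80 ± 0.15, edgeR adjusted p = 1.31e-12), and HUG1, an inhibitor of the same enzyme, from 5.36 ± 1.69 to 252 ± 39.8. Of 9 osmotic stress genes 7 were higher (median log2 fold change 1.34, camera adjusted p = 1.9e-05), with STL1, a glycerol importer, at 120.1-fold. HSP12, a small membrane heat shock protein, rose from 22.3 ± 6.16 to 1675 ± 66.7 CPM (log2 fold change 6.23 ± 0.32, edgeR adjusted p = 2.78e-08), though its list, the general stress response, had 6 higher and 2 lower of 20 (median log2 fold change 0.28, camera adjusted p = 0.077). Trehalose and glycogen genes had 2 higher of 16 (median log2 fold change 0.15, camera adjusted p = 0.11). Of the 15 genes in the list of repressors that recruit Tup1-Cyc8, which also holds TUP1, 9 were higher (median log2 fold change 1.42, camera adjusted p = 1.8e-05, adjusted p = 0.055 with an estimated correlation), such as NRG1 at 9.53-fold and SUT1 at 13.3-fold. No call by edgeR fell on the 11 Swi-Snf subunit genes (median log2 fold change -0.05, camera adjusted p = 0.39), with 2 higher and 5 lower at an unadjusted p below 0.05 and none called by DESeq2 or limma-voom. INO1, which encodes inositol phosphate synthase, was 2.98-fold higher (log2 fold change 1.57, edgeR adjusted p = 7.28e-05).

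Phosphate and mating genes were lower in the libraries labelled cyc8. In the phosphate regulon 10 of 15 genes were lower and 1 was higher (median log2 fold change -1.82, camera adjusted p = 1.7e-06, adjusted p = 0.062 with an estimated correlation). PHO84 (chromosome XIII, 23886 to 25919) decreased (log2 fold change -4.19 ± 0.41, edgeR adjusted p = 9.58e-06), and so did SPL2, a regulator of phosphate uptake, at 34.4-fold lower, and PHM6 at 83.2-fold lower. PHO5, a secreted acid phosphatase, was also lower (log2 fold change -4.12 ± 0.30, edgeR adjusted p = 4.05e-07), though 70.2% of its model overlaps another on the same strand. The higher member, named after its values were seen, was PHO89, a sodium-phosphate cotransporter, at 573 ± 141 against 41.0 ± 2.32 CPM. Genes specific to a cells were lower in 5 of 7 cases (median log2 fold change -1.61, camera adjusted p = 8.8e-06, adjusted p = 0.051 with an estimated correlation). STE2, the receptor for alpha factor, had 148 ± 12.3 against 553 ± 38.7 CPM (log2 fold change -1.90 ± 0.11, edgeR adjusted p = 6.16e-09), and BAR1, the protease that degrades alpha factor, was 16.7-fold lower. Of 12 pheromone response genes 5 were lower (median log2 fold change -1.03, camera adjusted p = 4.9e-05, adjusted p = 0.11 with an estimated correlation), such as FUS1, needed for cell fusion, at 10.0-fold lower. The 3 alpha-specific genes held 1 lower call, STE3 (median log2 fold change -0.51, camera adjusted p = 0.099). HO, the endonuclease of mating type switching, was 5.63-fold lower. DIP5, an amino acid permease, had 5.10 ± 1.19 against 166 ± 37.0 CPM (log2 fold change -5.01 ± 0.21, edgeR adjusted p = 1.13e-09).

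Sulfur and methionine genes were higher in 12 of 23 cases (median log2 fold change 1.04, camera adjusted p = 6.4e-06, adjusted p = 0.18 with an estimated correlation), for example SUL1, a sulfate permease, at 8.79-fold. The iron regulon had 10 higher and 2 lower of 20 (median log2 fold change 0.76, camera adjusted p = 0.14), and meiosis genes 5 higher and 2 lower of 20 (median log2 fold change 0.19, camera adjusted p = 0.091), with IME1, the inducer of meiosis, at 12.2-fold higher. Mitochondrially encoded genes held 2 higher and 1 lower of 8 (median log2 fold change 0.82, camera adjusted p = 0.039, adjusted p = 0.45 with an estimated correlation). Amino acid biosynthesis had 2 higher and 5 lower of 35 (median log2 fold change -0.06, camera adjusted p = 0.7). None of the 10 histone genes was called by edgeR, although the list shifted downward (median log2 fold change -0.48, camera adjusted p = 0.0014, adjusted p = 0.05 with an estimated correlation). No gene was called by edgeR among 137 ribosomal protein genes (median log2 fold change 0.04, camera adjusted p = 0.52), 36 ribosome biogenesis genes (median log2 fold change 0.09, camera adjusted p = 0.44) or 9 daughter cell separation genes (median log2 fold change -0.32, camera adjusted p = 0.15). At an unadjusted p below 0.05, histone genes counted 0 higher and 8 lower, ribosomal protein genes 30 higher and 16 lower, ribosome biogenesis genes 1 higher and 1 lower and daughter cell separation genes 0 higher and 4 lower, and DESeq2 and limma-voom called none of them. Of 182 genes within 20 kb of a chromosome end, 83 were higher and 12 lower (median log2 fold change 0.71, camera adjusted p = 1.3e-07, adjusted p = 0.062 with an estimated correlation). Adjusted over the list alone, 84 subtelomeric genes were higher, and every other list kept the counts given here.

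**Figure D2:**
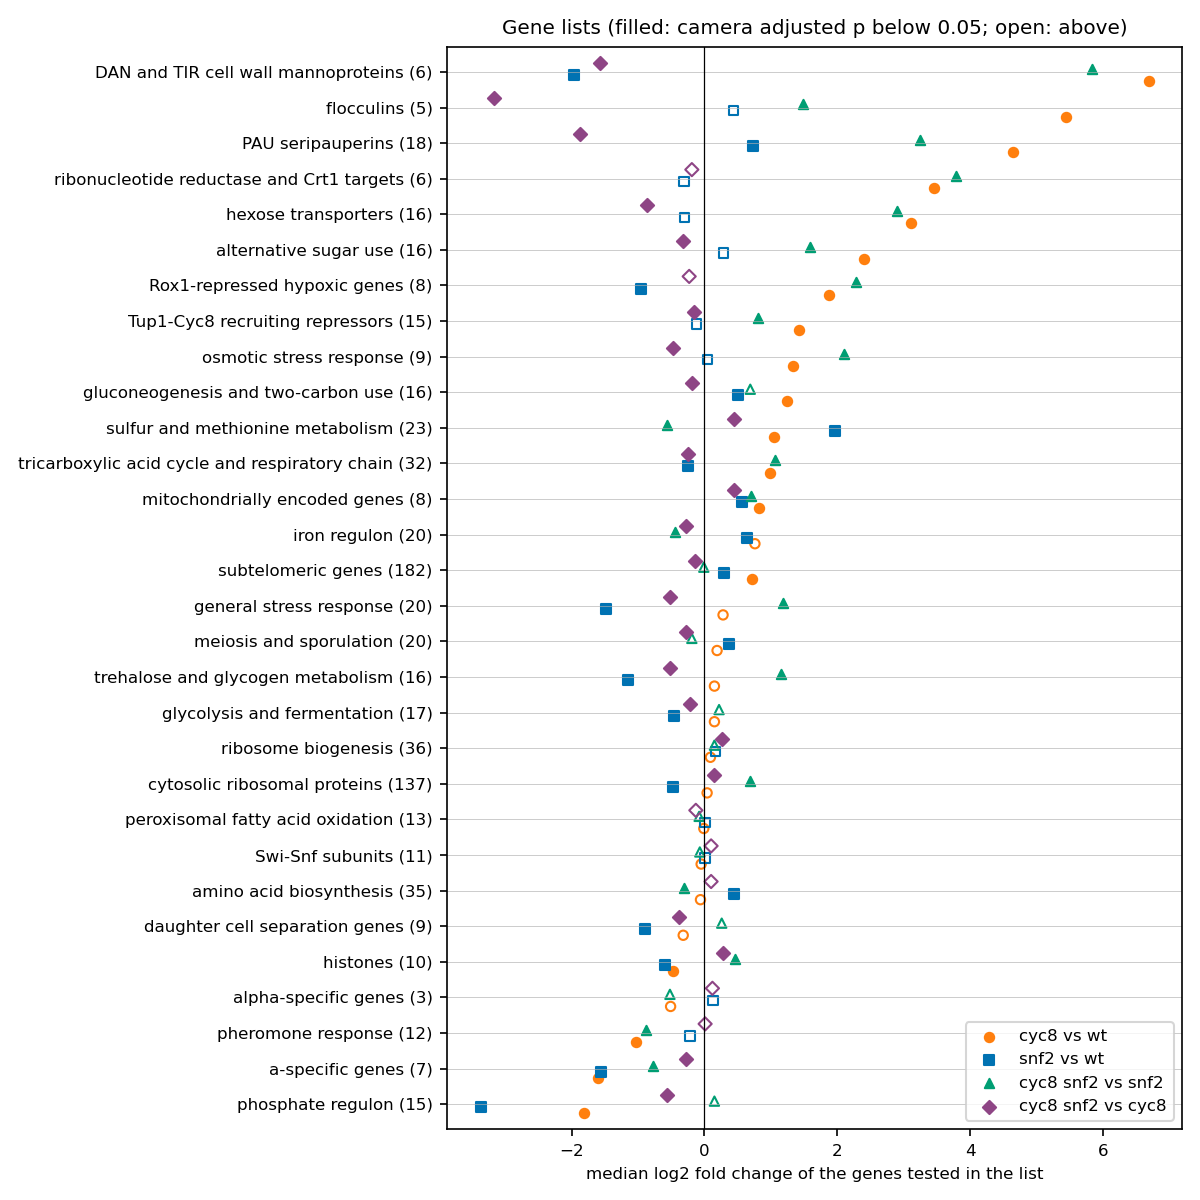
Median log2 fold change of each of the 30 gene lists (vertical axis, with the number of genes tested in cyc8 vs wt) in 4 comparisons, 1 symbol per comparison, filled where the camera adjusted p with the preset correlation is below 0.05. Flocculins stand at 5.45 in cyc8 vs wt and -3.17 in cyc8 snf2 vs cyc8, and the phosphate regulon at -3.37 in snf2 vs wt.

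The libraries labelled snf2 were compared with wt to ask which genes need Snf2. Phosphate, stress and reserve carbohydrate genes were lower, and sulfur amino acid genes and SER3 were higher. With an estimated correlation the calls of these lists were lost, at camera adjusted p = 0.051 for phosphate, 0.3 for stress, 0.38 for trehalose and glycogen and 0.12 for sulfur. PHO84 fell from 1235 ± 169.6 to 1.11 ± 0.158 CPM, 1103-fold. PTR2, the importer of small peptides, fell from 458 ± 124 to 4.90 ± 0.0200 CPM, and SER3, which encodes an enzyme that opens serine synthesis, rose from 50.7 ± 22.1 to 1077 ± 6.20 CPM. Of 6171 genes, 262 were higher and 333 lower. These groups differ in strain as well as in label, the SNF2 transcript was kept, and the share of non-coding counts was higher in both snf2 libraries, so the directions belong to the pair of groups and not to the mutation alone.

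Of 15 phosphate genes 14 were lower (median log2 fold change -3.37, camera adjusted p = 4.6e-17, adjusted p = 0.051 with an estimated correlation), led by PHO84 (log2 fold change -10.11 ± 0.69, edgeR adjusted p = 1.24e-06) and SPL2 at 189.9-fold lower. The model YNCM0001W (chromosome XIII, 23564 to 26578), which spans that of PHO84, rose from 1.55 ± 0.495 to 25.4 ± 1.53 CPM. Whether both changes are linked was not tested. Of 20 general stress genes 14 were lower (median log2 fold change -1.49, camera adjusted p = 1.4e-05, adjusted p = 0.3 with an estimated correlation), and HSP12 fell from 22.3 ± 6.16 to 1.27 ± 0.276 CPM (log2 fold change -4.12 ± 0.41, edgeR adjusted p = 2.08e-05). Trehalose and glycogen genes were lower in 9 of 16 cases (median log2 fold change -1.15, camera adjusted p = 9.8e-05, adjusted p = 0.38 with an estimated correlation), for example GSY1, a glycogen synthase, at 18.1-fold lower. Genes specific to a cells were lower in 4 of 7 cases (median log2 fold change -1.56, camera adjusted p = 3.4e-06, adjusted p = 0.1 with an estimated correlation) and DAN and TIR genes in 3 of 6 (median log2 fold change -1.96, camera adjusted p = 0.003, adjusted p = 0.3 with an estimated correlation), with TIR1 at 21.5-fold lower. HO was 26.3-fold lower. QDR2, a multidrug transporter, and RSB1, which exports sphingoid bases, were 75.8- and 33.1-fold lower. Daughter cell separation genes had 4 lower of 9 (median log2 fold change -0.90, camera adjusted p = 0.0011, adjusted p = 0.3 with an estimated correlation) and glycolysis 4 of 17 (median log2 fold change -0.46, camera adjusted p = 0.0019, adjusted p = 0.4 with an estimated correlation). The 137 ribosomal protein genes shifted downward without an edgeR call (median log2 fold change -0.47, camera adjusted p = 2.9e-18, adjusted p = 0.3 with an estimated correlation), with 2 higher and 116 lower at an unadjusted p below 0.05 and none called by DESeq2 or limma-voom.

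In the other direction, 18 of 23 sulfur and methionine genes were higher (median log2 fold change 1.97, camera adjusted p = 1.9e-13, adjusted p = 0.12 with an estimated correlation). SUL2, a sulfate permease, rose 14.7-fold and MET3, which activates sulfate, 10.8-fold (log2 fold change 3.44 ± 0.23, edgeR adjusted p = 5.06e-07). SER3 (chromosome V, 322213 to 324278) (log2 fold change 4.41 ± 0.32, edgeR adjusted p = 1.64e-06) has 26.6% of its model in an overlap with another on the same strand. The iron regulon had 6 higher and 1 lower of 20 (median log2 fold change 0.64, camera adjusted p = 0.0011, adjusted p = 0.38 with an estimated correlation), including FIT3, a wall mannoprotein that retains iron carriers, at 8.27-fold higher. The gluconeogenesis list had 4 higher and 1 lower of 16 (median log2 fold change 0.50, camera adjusted p = 0.00034, adjusted p = 0.1 with an estimated correlation), with SFC1, a mitochondrial carrier, at 20.3-fold higher. The flocculins held no call by edgeR, DESeq2 or limma-voom (median log2 fold change 0.44, camera adjusted p = 0.071), with 3 higher and 0 lower at an unadjusted p below 0.05. SUC2 stood at 122 ± 3.06 against 116 ± 12.7 CPM (log2 fold change 0.08 ± 0.11, edgeR adjusted p = 0.625). RNR3 also missed the test (log2 fold change -0.09 ± 0.15, edgeR adjusted p = 0.699). Adjusted over the list alone, the counts of every list named for these groups were unchanged. The snf2 means rest on 2 libraries.

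**Figure D3:**
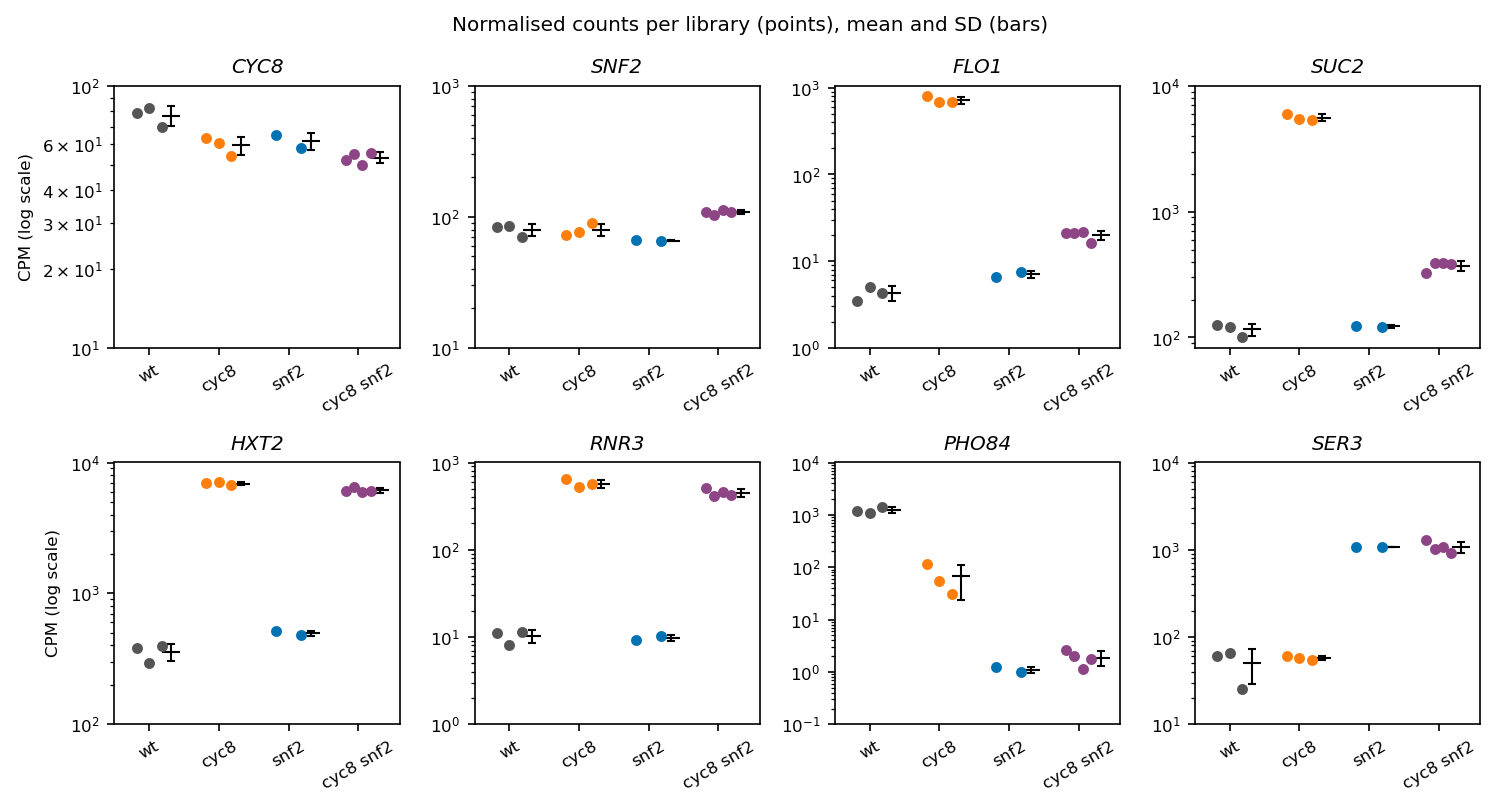
CPM per library on log scales for CYC8, SNF2 and 6 other genes, 1 point per library, with the group mean and SD as a bar beside the points. CYC8 and SNF2 are present in all groups, and FLO1 has a mean of 722 CPM in cyc8 and 19.9 CPM in cyc8 snf2.

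The double mutant was then compared with the libraries labelled snf2, which carry the same background label, to see what the cyc8 mutation does when Snf2 is also affected. Many genes that rose with the cyc8 label in the wild-type background rose here too. HXT2 went from 498 ± 21.5 to 6156 ± 266 CPM, 12.4-fold, and RNR3 from 9.72 ± 0.758 to 448 ± 44.6 CPM, 46.1-fold. FLO1 and SUC2 rose by less, to 19.9 ± 2.51 and 372 ± 31.1 CPM. PTR2, which was low in snf2, stood at 1017 ± 207 CPM in the double mutant. Of 6171 genes, 563 were higher and 190 lower in cyc8 snf2 than in snf2, and the transcripts of both mutated genes were present in these libraries. Upper-quartile scaling moved the median of all genes by -0.125, and the share of higher genes from 74.8 to 66.1%.

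DAN and TIR genes were higher in 5 of 6 cases (median log2 fold change 5.83, camera adjusted p = 3.5e-07, adjusted p = 0.086 with an estimated correlation), with TIR1 at 2419.8 ± 155 against 3.02 ± 0.365 CPM (log2 fold change 9.64 ± 0.21, edgeR adjusted p = 2.77e-12). PAU genes were higher in 14 of 18 cases (median log2 fold change 3.24, camera adjusted p = 9.5e-07, adjusted p = 0.065 with an estimated correlation). In the list of ribonucleotide reductase and Crt1 targets 5 of 6 were higher (median log2 fold change 3.79, camera adjusted p = 1.1e-06, adjusted p = 0.058 with an estimated correlation), among them RNR3 (log2 fold change 5.53 ± 0.17, edgeR adjusted p = 2.29e-11). Of 16 hexose transporters 11 were higher, with a median log2 fold change of 2.90, or 2.37 with the gene lacking counts in snf2 set to its bound (camera adjusted p = 1.7e-05, adjusted p = 0.065 with an estimated correlation). Genes for other sugars were higher in 12 cases and lower in 1 of 16 (median log2 fold change 1.59, camera adjusted p = 1.2e-07, adjusted p = 0.1 with an estimated correlation), and flocculins higher in 4 of 5 (median log2 fold change 1.49, camera adjusted p = 0.001, adjusted p = 0.089 with an estimated correlation). SUC2 rose 3.04-fold (log2 fold change 1.60 ± 0.11, edgeR adjusted p = 9.09e-08) and FLO1 2.80-fold (log2 fold change 1.49 ± 0.15, edgeR adjusted p = 3.82e-06). General stress genes were higher in 11 of 20 cases (median log2 fold change 1.19, camera adjusted p = 0.00077, adjusted p = 0.39 with an estimated correlation), and HSP12 rose 292-fold. PTR2 rose 207-fold (log2 fold change 7.70 ± 0.32, edgeR adjusted p = 4.06e-09) and RSB1 298-fold. Respiratory genes were higher in 19 cases and lower in 1 of 32 (median log2 fold change 1.06, camera adjusted p = 1.3e-08, adjusted p = 0.22 with an estimated correlation), and ribosomal protein genes in 3 of 137 (median log2 fold change 0.68, camera adjusted p = 4e-23, adjusted p = 0.25 with an estimated correlation).

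Among the genes lower in the double mutant than in snf2, DIP5 had 1.83 ± 0.433 against 232 ± 3.23 CPM (log2 fold change -7.00 ± 0.22, edgeR adjusted p = 1.05e-10). CIT2, the peroxisomal citrate synthase, was 20.6-fold lower and DLD3, a lactate dehydrogenase, 7.82-fold lower. ARG1, an enzyme of arginine synthesis, was 8.10-fold lower (log2 fold change -3.02, edgeR adjusted p = 2.22e-09). Sulfur genes were lower in 5 of 23 cases (median log2 fold change -0.56, camera adjusted p = 0.0016, adjusted p = 0.39 with an estimated correlation) and pheromone genes in 4 of 12 (median log2 fold change -0.88, camera adjusted p = 0.0022, adjusted p = 0.25 with an estimated correlation). Phosphate genes had 4 higher and 2 lower of 15 (median log2 fold change 0.15, camera adjusted p = 0.53), and PHO84 stayed at 1.88 ± 0.605 against 1.11 ± 0.158 CPM. SER3 had 1079 ± 159 against 1077 ± 6.20 CPM (log2 fold change 0.00 ± 0.28, edgeR adjusted p = 0.992). The counts of the lists named for these groups were unchanged when adjusted over the list alone.

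The direct comparison of the double mutant with the libraries labelled cyc8 asks which genes that rise without Cyc8 need Snf2 for their high level. Flocculin, PAU and some sugar genes were far lower in the double mutant, while HXT2 and RNR3 kept most of their level. FLO1 fell from 722 ± 67.0 to 19.9 ± 2.51 CPM, 36.3-fold, and SUC2 from 5599.6 ± 353 to 372 ± 31.1 CPM, 15.1-fold. HXT17 fell from 610.3 ± 52.6 to 7.53 ± 1.47 CPM. HXT2 had 6156 ± 266 against 6907 ± 133 CPM, and RNR3 448 ± 44.6 against 574 ± 61.1. Of 6171 genes, 57 were higher and 186 lower in cyc8 snf2 than in cyc8. Strain and label changed together here, and SNF2 had the higher CPM in the group labelled with its mutation. The cyc8 mutation may differ as well, as URA3 marks it only in the double mutant. Without cyc8 replicate 3, the count of higher genes was 38.

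Flocculins were lower in 4 of 5 cases (median log2 fold change -3.17, camera adjusted p = 1.5e-09), FLO1 (log2 fold change -5.18 ± 0.13, edgeR adjusted p = 4.3e-12) and FLO11 (log2 fold change -4.58 ± 0.20, edgeR adjusted p = 8.49e-09) among them. PAU genes were lower in 11 of 18 cases (median log2 fold change -1.87, camera adjusted p = 1.5e-09). PAU5 fell 37.6-fold and PAU13 63.3-fold (log2 fold change -5.98 ± 0.13, edgeR adjusted p = 9.59e-13). Hexose transporters were lower in 7 of 16 cases (median log2 fold change -0.87, camera adjusted p = 7.5e-07), with HXT17 (log2 fold change -6.33 ± 0.16, edgeR adjusted p = 2.07e-11) and HXT13 at 66.3-fold lower, while HXT2 did not pass the test (log2 fold change -0.17 ± 0.10, edgeR adjusted p = 0.245). All 6 DAN and TIR genes were lower (median log2 fold change -1.58, camera adjusted p = 6.4e-09, adjusted p = 0.068 with an estimated correlation), for example DAN1 at 3.04-fold lower. SUC2 (log2 fold change -3.91 ± 0.10, edgeR adjusted p = 4.3e-12) was 1 of 2 lower genes among 16 for other sugars (median log2 fold change -0.33, camera adjusted p = 0.00067, adjusted p = 0.32 with an estimated correlation). TIP1, a wall mannoprotein, fell 32.1-fold and HSP26, a small heat shock chaperone, 25.9-fold (log2 fold change -4.69 ± 0.26, edgeR adjusted p = 2.85e-07). General stress genes were lower in 4 of 20 cases (median log2 fold change -0.52, camera adjusted p = 6.6e-05, adjusted p = 0.32 with an estimated correlation), 5 when adjusted over the list alone, which left the other lists named for these groups unchanged.

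Subtelomeric genes were lower in 25 and higher in 3 of 182 cases (median log2 fold change -0.14, camera adjusted p = 0.0004, adjusted p = 0.32 with an estimated correlation). No gene was called by edgeR, DESeq2 or limma-voom among the 6 ribonucleotide reductase and Crt1 targets (median log2 fold change -0.19, camera adjusted p = 0.5) and the 8 Rox1-repressed genes (median log2 fold change -0.23, camera adjusted p = 0.17), where 1 higher and 2 lower and 0 higher and 3 lower passed an unadjusted p below 0.05. RNR3 differed by less than 2-fold (log2 fold change -0.36 ± 0.11, edgeR adjusted p = 0.0375). The 10 histone genes were shifted upward without a call by these tools (median log2 fold change 0.28, camera adjusted p = 1.3e-05), with 7 higher and 0 lower at an unadjusted p below 0.05. Phosphate genes were lower in 6 of 15 cases (median log2 fold change -0.56, camera adjusted p = 1.6e-05, adjusted p = 0.15 with an estimated correlation), PHO84 by 35.3-fold. The size of the PHO84 fold is uncertain, as the cyc8 libraries ranged from 31.25 to 117.6 CPM. Meiosis genes had 1 higher and 4 lower of 20 (median log2 fold change -0.28, camera adjusted p = 0.011, adjusted p = 0.094 with an estimated correlation), with IME1 at 5.13-fold lower. Apart from the marker genes, the largest rise among called genes with a mean of at least 10 CPM in either group was that of SER3, 18.8-fold (log2 fold change 4.23 ± 0.30, edgeR adjusted p = 2.41e-06), the gene that was also high in snf2.

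Of the 640 genes higher in cyc8 than in wt, 118 (18.4%) were lower in the double mutant than in cyc8, 8 were higher and 514 were not called. Independent lists of these lengths would share 19.3 lower genes. The cyc8 libraries stand in both comparisons, so part of the excess may come from them. Simulations of unchanged groups shared 0 genes but do not measure that part, as they held at most 3 calls over all 6 comparisons. The covariance of the log2 fold changes of both comparisons was -0.263, against a mean of -0.022 in 20 such simulations, and Pearson's r was -0.36, against -0.544. Among the 168 genes at least 8-fold higher in cyc8, 66 (39.3%) were lower in the double mutant, FLO1, SUC2 and HXT17 among them. Of the 118 genes, 82 were still higher in the double mutant than in snf2 and 32 were not called against it. Of the 640, 381 (59.5%) were higher in the double mutant than in snf2, a comparison with no library in common, and the median log2 fold change of the 640 there was 1.26. Between the single mutants, 131 genes were higher than in wt in both and 111 lower in both, where independent lists would share 27.2 and 11.6. Opposite calls fell on 77 genes higher in cyc8 and lower in snf2 and on 10 lower in cyc8 and higher in snf2, where independent lists would share 34.5 and 9.1. The wt libraries stand in both comparisons, so part of the shared directions may come from them. The covariance was 0.238, against a mean of 0.02 in the simulations, and r was 0.234, against 0.447. With r the observed values of both pairs were thus nearer to 0 than the simulated ones, and with the covariance farther from it.

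The double mutant was also compared with wt. Wall, sugar and DNA damage genes were higher and phosphate genes lower by the test with the preset correlation, and none of the list calls given for these groups held with an estimated correlation. Of 6171 genes, 599 were higher and 245 lower. Flocculins were higher in 3 of 5 cases (median log2 fold change 2.22, camera adjusted p = 0.00023, adjusted p = 0.057 with an estimated correlation), DAN and TIR genes in 5 of 6 (median log2 fold change 4.84, camera adjusted p = 1.2e-05, adjusted p = 0.098 with an estimated correlation), genes for other sugars in 11 of 16 (median log2 fold change 1.86, camera adjusted p = 6.7e-08, adjusted p = 0.098 with an estimated correlation) and the ribonucleotide reductase and Crt1 targets in 4 of 6 (median log2 fold change 3.34, camera adjusted p = 1.2e-05, adjusted p = 0.052 with an estimated correlation). Of 16 hexose transporters 11 were higher and 1 lower, with a median log2 fold change of 2.12, or 1.84 with the gene lacking counts in wt set to its bound (camera adjusted p = 4.9e-05, adjusted p = 0.052 with an estimated correlation). PAU genes were higher in 15 of 18 cases (median log2 fold change 3.99, camera adjusted p = 2.4e-09, adjusted p = 0.052 with an estimated correlation), and IMA1 was 63.9-fold higher. HXT2 was 17.2-fold higher (log2 fold change 4.10 ± 0.11, edgeR adjusted p = 3.76e-12) and SUC2 reached 372 ± 31.1 against 116 ± 12.7 CPM (log2 fold change 1.68 ± 0.10, edgeR adjusted p = 6.23e-09). RCK1, a protein kinase of the oxidative stress response, rose from 2.57 ± 1.11 to 466 ± 76.3 CPM, and SGA1, a glucoamylase, from 1.07 ± 0.250 to 88.1 ± 8.66. Phosphate genes were lower in 13 of 15 cases and higher in 1 (median log2 fold change -2.08, camera adjusted p = 1.3e-09, adjusted p = 0.052 with an estimated correlation), and PHO84 had 1.88 ± 0.605 CPM (log2 fold change -9.33 ± 0.48, edgeR adjusted p = 4.03e-08). Sulfur genes were higher in 15 of 23 cases (median log2 fold change 1.42, camera adjusted p = 4.1e-08, adjusted p = 0.12 with an estimated correlation) and a-specific genes lower in 5 of 7 (median log2 fold change -1.93, camera adjusted p = 2.9e-06, adjusted p = 0.052 with an estimated correlation). SER3 was 21.3-fold higher (log2 fold change 4.41, edgeR adjusted p = 3.72e-07). The counts of the lists named for these groups were unchanged when adjusted over the list alone. Strain and label again changed together, and neither CYC8 nor SNF2 was lost.

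The last comparison asked whether the change with the cyc8 label differed between the backgrounds with and without the snf2 label, as an interaction in which a constant strain difference cancels. A difference between the cyc8 mutations of both backgrounds would not cancel. URA3 marks that mutation in the double mutant and had no count in the cyc8 libraries. FLO1 rose 169-fold with the cyc8 label in the wild-type background and 2.80-fold beside the snf2 label, and SUC2 48.3- and 3.04-fold. PTR2, low in snf2, rose 207-fold beside the snf2 label. Across the 6171 genes, the log2 fold changes of cyc8 against wt and of cyc8 snf2 against snf2 rose together, with Pearson's r of 0.704 and Spearman's rho of 0.523 (permutation p = 0.0001 for each, the smallest that 9999 permutations can give). Genes are not independent replicates, and r was 0.698 without the 2 genes farthest from the median. The slope was 0.634. The change differed for 549 genes, 259 with a higher and 290 with a lower change where the snf2 label was present. Of the 259, 198 were called lower in snf2 than in wt, and of the 290, 166 were called higher there. The wt and snf2 libraries (snf2 n = 2) enter both tests, so part of these differences may be the gap between snf2 and wt itself. The labelled genes kept their transcripts here too.

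**Figure D4:**
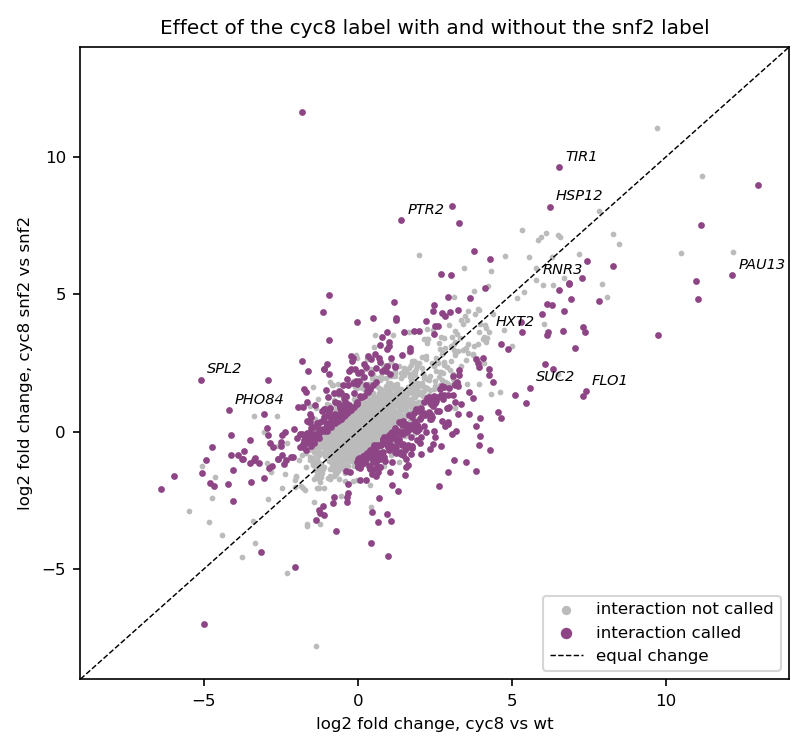
Log2 fold change of each of the 6171 genes in cyc8 vs wt (horizontal) and in cyc8 snf2 vs snf2 (vertical), 1 point per gene, purple where the difference between both was called, with a dashed line of equal change. FLO1 lies at 7.40 and 1.49, below the line, and PTR2 above it with an interaction of 6.28. The highest point at the left is URA3, a marker gene.

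FLO1 had an interaction of -5.91 ± 0.20 (log2 scale, edgeR adjusted p = 5.85e-10) and SUC2 of -3.99 ± 0.14 (edgeR adjusted p = 6.77e-10). PAU13, PAU5 and FLO11 were at -6.45, -6.21 and -4.40, and SFC1 at -4.95. All 5 flocculins (median log2 difference -3.61, camera adjusted p = 9.9e-08) and 10 of 18 PAU genes (median log2 difference -3.32, camera adjusted p = 5.8e-09) had a called interaction below 0, 11 of the latter when adjusted over the list alone. Sulfur genes were called below 0 in 17 of 23 cases (median log2 difference -1.55, camera adjusted p = 3.6e-10, adjusted p = 0.12 with an estimated correlation), with a list median of 1.04 in cyc8 against wt and -0.56 in the double mutant against snf2, and BNA2, which opens the synthesis of NAD from tryptophan, had an interaction of -4.34. In the phosphate regulon 12 of 15 genes had a called interaction above 0 (median log2 difference 2.05, camera adjusted p = 3.1e-14), PHO84 at 4.97 ± 0.79 (edgeR adjusted p = 0.00112). PHO84 stood at 1.11 CPM in snf2 and 1.88 CPM in the double mutant, so beside the snf2 label it had little room to fall. PTR2 (log2 difference 6.28 ± 0.35, edgeR adjusted p = 2.31e-07), QDR2 at 5.47 and RSB1 at 5.18 were low in snf2 and rose in the double mutant, QDR2 from 1.53 to 31.2 CPM, which is below its 116 CPM in wt. Histone genes had 5 calls of 10, all above 0 (median log2 difference 0.94, camera adjusted p = 9.9e-08), with HHF1 at 1.40. HXT2 (log2 difference -0.64 ± 0.15, edgeR adjusted p = 0.00625) and RNR3 (log2 difference -0.27 ± 0.19, edgeR adjusted p = 0.318) did not pass the threshold of the difference.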

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

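All tests of explanations in this part were chosen after the results were seen. The change with the cyc8 label differed between the backgrounds with and without the snf2 label, by a test of the difference itself, for 259 genes upward and 290 downward. Of these, 198 and 166 were also called the opposite way in snf2 against wt, and the snf2 libraries (n = 2) enter both tests. Among the lists, the median difference on the log2 scale was -3.61 for flocculins, -3.32 for PAU genes, -0.69 for other sugars, -0.86 for gluconeogenesis, -1.30 for the iron regulon, -0.66 for meiosis, -1.55 for sulfur and methionine and -0.43 for subtelomeric genes. It was 2.05 for the phosphate regulon, 1.24 for a-specific genes, 0.63 for ribosomal proteins and 0.94 for histones. With an estimated correlation the calls of flocculins, PAU genes, gluconeogenesis, phosphate, meiosis and histones held, and the others gave camera adjusted p = 0.3 (other sugars), 0.29 (iron), 0.076 (a-specific), 0.29 (ribosomal proteins), 0.12 (sulfur) and 0.11 (subtelomeric). Among named genes the difference was -5.91 for FLO1, -4.40 for FLO11, -6.45 for PAU13, -6.21 for PAU5, -3.99 for SUC2, -4.34 for BNA2 and -4.95 for SFC1. It was 6.28 for PTR2, 5.47 for QDR2, 5.18 for RSB1, 4.97 for PHO84 and 1.40 for HHF1.

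The 118 genes that were higher in cyc8 than in wt and lower in the double mutant than in cyc8 are the first pattern weighed. A constant difference between strain backgrounds would lower the same genes in snf2 against wt by at least 2-fold, but over the 87 genes with a wt mean of at least 1 CPM the median there was -0.36 (95% bootstrap interval -0.87 to -0.15), against -1.70 in the double mutant against cyc8. The 31 genes with a lower wt mean were not used for this. The wt libraries helped to pick the genes as higher in cyc8, which pushes their change in snf2 against wt upward. The genes were also picked as lower in the double mutant than in cyc8, so the gap between both medians may be too large. A constant effect of the snf2 mutation would lower them in snf2 in the same way as the strain. Reads shared between near-identical copies cannot account for 82 of the 118 genes, which hold no repeated 50-base word. Of the 522 other genes higher in cyc8, 448 hold none. Genes with repeated words are thus more frequent in the pattern, and for them shared reads stay possible. A strain difference that acts only where Cyc8 is affected may remain. So may a difference between the cyc8 mutations of both groups, as URA3 marks only that of the double mutant. A need for Snf2 at these genes also remains, untested apart from strain and from the cyc8 mutation used.

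The 595 genes called between snf2 and wt are the second pattern. A constant strain difference would move them as far between the double mutant and cyc8, but the median there was -0.50 (-0.60 to -0.37) over the 333 lower genes and 0.10 (0.04 to 0.20) over the 262 higher genes. A constant effect of the snf2 mutation would give the same shift, as both comparisons differ by strain and by that label, so these medians cannot tell strain from mutation. The genes were picked for large changes in snf2 against wt, so smaller ones elsewhere are likely. The intervals resample genes, not libraries. A single deviating snf2 library is argued against by 425 of the 595 genes, which were called in the same direction both without snf2 replicate 1 and without snf2 replicate 2. The strain may still account for single genes or for part of each median, and the mutation itself also stays open.

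The lower a-specific genes in cyc8 are the third pattern, with a median of -1.61. Cells of type a/alpha with working Cyc8 would lower haploid genes as far, and 10 such genes had a median of -0.30 (-0.93 to -0.16, from resampled genes). If that repression itself needs Cyc8, cells labelled cyc8 would not show it, so these genes cannot decide on a/alpha cells. Among the 10 genes HO, at -2.49, fell farther and FAR1, at -1.54, nearly as far, while the others lay between -0.77 (GPA1) and 0.47 (NEJ1). Alpha cells in place of a cells would raise alpha-specific genes at least 2-fold, but the median of the 3 tested was -0.51 (-0.31 for the median of the values plus 2 SE), with STE3 at -2.05 ± 0.25, SAG1 at -0.51 ± 0.10 and MF(ALPHA)1, near 0 CPM, at 0.32 ± 0.72. This bound replaced, after the values were seen, the stricter one that each gene plus 2 SE lie below 1, which MF(ALPHA)1 missed and which had left alpha cells open, and alpha cells that do not express these genes are not excluded by either. A change with the cyc8 mutation may be the source, as the design allows, and stays a hypothesis found and tested on the same data.

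Other splits of the libraries were compared with the real ones. For cyc8 against wt 10 splits are too few for a share under 0.05, with 855 genes in the real split, which was the only 1 with as many, and 0 in the highest other. For the double mutant against wt, the real split, with 844 genes, was the only 1 of 35 with as many, and the highest other gave 188. Against cyc8, the real split, with 243, was again the only 1 of 35 with as many, and the highest other gave 6. A share of 1 in 35 is the smallest that these splits can give. All other splits mix both labels within a group, which widens the spread there, so few calls in them were likely in advance. The splits therefore do not decide on chance.

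In the double mutant, 1 library stood apart from the others for 3 of 28 genes looked at, where chance gives about 1 in 20. FLO1 had 16.1 CPM in replicate 4 against 20.9 to 21.5 in the others, HXT2 6550 CPM in replicate 2 against 5990 to 6040, and SUC2 325 CPM in replicate 1 against 383 to 391.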

How the results depend on the processing

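The alternative with protein-coding genes only was chosen after the results were seen. No list call reversed under any alternative run, and for the 97 values of named genes neither the call, which needs both thresholds, nor the direction of a called gene changed with other scalings, filters and tools, the block or a library left out. The adjusted p alone crossed 0.05 for SNF2 in snf2 against wt (0.00839 to 0.185) and RNR3 in the double mutant against cyc8 (0.0139 to 0.152), both under 2-fold. Values near 0 that were not called changed sign for MF(ALPHA)1 in cyc8 against wt (-0.21 to 0.81, where it passed the filter), SER3 in the double mutant against snf2 (-0.12 to 0.23) and SUC2 in snf2 against wt (-0.01 to 0.13). Of the 112 list calls, camera with an estimated correlation lost 96, fry 5, the replicate block 3 and RLE scaling 1, and leaving out single libraries lost 20 of 1344. Calls that held in each of the 12 fits without 1 library were 702 of 855 in cyc8 against wt, 410 of 595 in snf2 against wt, 687 of 844 in the double mutant against wt, 567 of 753 against snf2, 174 of 243 against cyc8 and 369 of 549 in the interaction. DESeq2 also called 841, 581, 838, 735, 241 and 543 of them. Where a library of snf2 was left out, the lone one was assumed to vary like the other groups. Keeping ribosomal RNA tested nothing, as these genes held 2 counts.

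Thresholds set the counts by construction. In the order above, genes higher and lower without a minimum fold change were 1413 and 1477, 1065 and 1151, 1564 and 1579, 1502 and 1467, 532 and 643, and 848 and 781, and with a minimum log2 fold change of 2 they were 294 and 70, 86 and 145, 259 and 87, 271 and 45, 11 and 66, and 93 and 98. The cyc8-higher genes lower in the double mutant than in cyc8 were 364 and 44, and those lower in snf2 than in wt 230 and 27. At an adjusted p below 0.01, 36 genes were higher in the double mutant than in cyc8. Without the low-count filter the correlation was 0.563, with more genes tested, and the cause was not tested further.

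Without 1 library, genes higher ranged from 604 to 669, 206 to 283, 576 to 623, 514 to 571, 38 to 57 (38 without cyc8 replicate 3) and 205 to 274, and genes lower from 193 to 225, 282 to 356, 238 to 258, 163 to 192, 173 to 193 and 260 to 306. The 118 genes became 114 to 125, the 77 genes 67 to 80 and r 0.673 to 0.708. The replicate numbers do not pair the libraries: over 15 same-numbered pairs the deviations correlated at -0.237 to 0.305, 1 pair was over 0.1 and 1 library correlated best with its own number. The 38 other pairs ranged wider, from -0.499 to 0.541. A factor shared by differently numbered libraries of different groups stays possible and was not modelled. With the replicate block the counts were 639 and 211, 254 and 340, 591 and 250, 560 and 198, 44 and 178, and 251 and 289, with 119, 82 and r of 0.701. With protein-coding genes only they were 569 and 167, 232 and 274, 509 and 208, 470 and 164, 39 and 175, and 206 and 268, with 109, 72 and r of 0.731.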

Other observations

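Chosen after the values were seen were the gene classes and genes of the next paragraphs and all tests of TATA boxes and chromosome ends other than those of the 118 genes against the other genes higher in cyc8. No test compared any of these classes with other genes. Of the retrotransposon genes for Ty gag-pol proteins, those called against wt were all lower, 26 of 32 in cyc8 (median log2 fold change -2.37), 22 in snf2 (-1.96) and 28 in the double mutant (-3.17) against wt by edgeR. All 32 have over 50% repeated words, so single copies are uncertain. Transfer RNA genes were lower in 23 and higher in 1 of 76 cases in snf2 against wt (median -1.10) and higher in 27 of 76 in the double mutant against snf2 (median 1.33), and 66 of them have over 50% repeated words. The snf2 libraries also had the highest non-coding shares, 16.9 and 17.5%. Small nucleolar RNA genes were lower in 10 and higher in 1 of 53 cases in cyc8 against wt. In the double mutant 6 were higher and 9 lower than in wt (median -0.05), and 4 were higher and 0 lower than in cyc8. The interaction was called above 0 for 9 of them and below 0 for 0.

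Some members of 3 further classes were called. Of 19 amino acid permeases and transporters 5 were higher and 2 lower in cyc8 than in wt, 3 and 3 in snf2, and 5 and 5 in the double mutant, and 7 were lower and 1 higher in the double mutant than in cyc8. Of 20 thiamine and vitamin B6 genes 8 were higher in cyc8 than in wt. Of 16 ion and polyamine exporters 8 were higher and 1 lower in cyc8, 5 were lower in snf2, and 6 were higher and 1 lower in the double mutant than in snf2.

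A hypothesis was that a TATA box or nearness to a chromosome end goes with the lower level of the 118 genes in the double mutant. The sequence TATAWAWR lay within 200 bp upstream of 48 of 110 of these genes (43.6%) and of 154 of 456 other genes higher in cyc8 (33.8%), an odds ratio of 1.52 (95% interval 0.97 to 2.37, two-sided Fisher exact p = 0.06, adjusted p = 0.14 over 7 tests). Nearness within 20 kb applied to 21 of 118 (17.8%) against 62 of 522 (11.9%), an odds ratio of 1.60 (0.89 to 2.82, p = 0.095, adjusted p = 0.17, same exact test). Both intervals hold 1 and reach over 1.5, so neither an association nor its absence is shown. Among genes without repeated words the second ratio was 1.15 (5 of 82 against 24 of 448). Among genes at least 8-fold higher in cyc8 the TATA ratio was 1.44 (0.71 to 2.95).

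Genes higher in cyc8 as a whole had a TATA box in 202 of 566 cases (35.7%), against 986 of 5138 (19.2%) for the other protein-coding genes tested, an odds ratio of 2.34 (1.93 to 2.82, Fisher exact adjusted p = 2.1e-17). Genes lower in cyc8 had one in 19.3% of cases, an odds ratio of 1.01 (0.66 to 1.50) against 19.2% of genes not called. Of the 640 higher genes 83 (13.0%) lay within 20 kb of a chromosome end, against 99 of 5531 (1.8%), an odds ratio of 8.17 (Fisher exact adjusted p = 1.3e-34). Most of these 83 genes hold repeated words, and the reads of such genes are uncertain. Of the higher genes without such words, 5 of 82 (6.1%) that were lower in the double mutant and 24 of 448 others (5.4%) lay there. The ratio of higher genes without repeated words against other such genes was not computed, so how far the excess rests on repeated words is open. Neighbouring and related genes are not independent, so these p-values are too small by an unknown amount.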
